A study of Mus musculus with 18 samples.

How the data were processed

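RNA sequencing was read from 1 deposited table of normalised values for 18 libraries of mouse bone marrow derived macrophages, 3 for each of 6 groups of genotype (WT or p110g-/-) and stimulus (M-CSF, IFNg/LPS or IL-4). Per the labels, mice were C57BL/6 and 8 weeks old, marrow was cultured for 6 days in 50 ng/ml M-CSF, and cells were then stimulated for 24 h (M-CSF at 20 ng/ml, alone or with IFNg and 100 ng/ml LPS) or for 48 h (M-CSF at 20 ng/ml with 20 ng/ml IL-4). The IL-4 libraries therefore differ from the M-CSF libraries in time as well as stimulus. Per the labels, the authors isolated total RNA, sequenced it on an Illumina HiSeq instrument, and used CASAVA 1.8.2, Bowtie2 and DESeq with genome build mm9, without giving the counting method or the versions of the last 2 tools. The deposited values are in the unit signal: gene read counts divided by 1 factor per library and rounded to 1 decimal. That reading rests on the values, because every value of a library was a whole multiple of 1 step to within 0.1, so whole reads could be recovered. The table holds 16474 genes, 1232 of them at 0 in at least 1 library and none at 0 in all.

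Recovered reads per library in M (1e6), numbers 1, 2 and 3, were 59.5, 52.8 and 43.1 M in WT M-CSF, 45.8, 69.6 and 40.6 M in WT IFNg/LPS, 53.5, 59.1 and 40.6 M in WT IL-4, 40.1, 42.3 and 49.9 M in p110g-/- M-CSF, 54.0, 64.0 and 62.6 M in p110g-/- IFNg/LPS, and 68.1, 48.8 and 63.1 M in p110g-/- IL-4. Between 128 and 307 genes per library were at 0. A gene at 0 held no read, but its expected count may have been up to 3 reads, a value of 2.15 to 4.74. Genes with a group at or under that level are therefore given by level and without a fold. The gene with the most reads was Ctsb, Psap or Fth1, with at most 3.34% of the reads of a library. The labels do not say how reads shared between near-identical gene copies, or the strand, were handled, so values of members of such families (H60a, Raet1 and Gbp genes, Chi3l3, Erdr1 and the zinc finger gene Etohi1) are uncertain in that respect.

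Groups, comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. The exceptions are the fits, tests and listings that the text names as chosen after the data were seen. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, as a model of 6 group means over all 18 libraries (12 residual degrees of freedom) with trend and robust variance moderation. The 15627 genes with a value of at least 10 in at least 3 libraries were tested, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at 0.05. The comparisons were p110g-/- against WT under each stimulus, each stimulus against M-CSF within a genotype, and the difference of the genotype effect between a stimulus and M-CSF (the interaction). The 2 interactions share the M-CSF libraries, as do the responses to the 2 stimuli of a genotype, which were therefore not compared with each other. Log2 fold changes are p110g-/- minus WT, or stimulus minus M-CSF. Genes named in the text come from a fixed list of 26 genes, from the largest differences with complete separation of 3 libraries from 3 and a mean of at least 50, from the 5 smallest adjusted p per direction of an interaction, and from up to 4 members with the smallest p of each gene list. Complete separation of 3 from 3 arises for 1 of 10 groupings by chance.

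Gene groups were tested with camera at an inter-gene correlation of 0.01, and again with an estimated correlation. Fry, which tests a list by itself, was run as an alternative. Adjustment was over the 27 tested of 28 lists (503 of 536 symbols tested). They were inflammatory cytokines and chemokines, alternative activation markers, immune suppressive and tissue repair factors, MHC class II, MHC class I, type I interferon-stimulated genes, interferon gamma-induced GTPases, NF-kB, PI3K pathway, cell cycle, glycolysis and hypoxia, sterol synthesis, LXR targets and lipid handling, lysosome, oxidative stress, unfolded protein and stress response, complement and scavenger genes, migration, macrophage identity, handling stress, and markers of neutrophils, dendritic cells, B cells, T and NK cells, fibroblasts, mast cells and osteoclasts. Erythroid markers had too few tested members. Genes called by a stimulus in WT were tested as sets, by camera, in the genotype effect of the other stimulus, which shares no library with the set.

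The labels give each group the numbers 1 to 3 without saying what a number marks. A check of deviations from the group means, made before calls were compared, treated the numbers as pairs where every same-numbered pair correlated above 0.1. This held for the genotype effect in IFNg/LPS (correlations 0.546, 0.340 and 0.256), the IFNg/LPS response in WT (0.256, 0.191 and 0.162) and the IL-4 response in WT (0.458, 0.347 and 0.179) and p110g-/- (0.397, 0.248 and 0.187), so fits with the number as a block (10 residual degrees of freedom) are given there where they change the call of a gene or list in the text. Member counts of lists come from the fit without the block unless stated. The check did not hold for the other comparisons.

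Alternatives to the pseudocount, the filter, the normalization, the tool (edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads), the variance model, library weights, the block, the libraries in the fit and each library left out in turn were run for every comparison. After the data were seen, fits of the libraries numbered 2 and 3 only and edgeR with the block were added. The whole method was tested on simulated data built from the libraries, where it recovered 97.0%, 95.5% and 97.0% of 4-fold changes, 74.2%, 80.3% and 69.7% of 2-fold changes and 50%, 48.5% and 55.9% of 1.5-fold changes in M-CSF, IFNg/LPS and IL-4. Of the genes called there, 10 of 157, 8 of 157 and 6 of 154 were unchanged genes. Each simulation changed 200 genes, fewer than the 2303 that passed between the genotypes in IFNg/LPS. For gene neighbours on chromosomes the order of genes in RefSeq on assembly GRCm38.p6 was used, and no coordinate is printed because the authors aligned to mm9. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.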

Results

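RNA was measured by sequencing in macrophages grown from the bone marrow of 8-week-old C57BL/6 mice that were either wild type (WT) or p110g-/-, the label for loss of p110gamma, the catalytic subunit of phosphoinositide 3-kinase gamma that Pik3cg encodes. Marrow cells were grown for 6 days in 50 ng/ml M-CSF, the growth factor of macrophages. They were then kept in 20 ng/ml M-CSF alone for 24 h, in M-CSF with interferon gamma (IFNg) and 100 ng/ml lipopolysaccharide (LPS) for 24 h, or in M-CSF with 20 ng/ml interleukin 4 (IL-4) for 48 h. Each of the 6 groups of genotype and stimulus held 3 libraries, numbered 1 to 3, which gives 18 libraries. The table lists 16474 genes, and each library held between 40.1 and 69.6 M (1e6) reads over them. A value is a gene's normalised signal, and group values are means ± SD over 3 libraries. A gene at 0 in a library held no read there. Its expected count may still have been up to 3 reads, a signal of 2.15 to 4.74 depending on the library. Intervals and floors of this kind cover counting error only. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so the p-values measure the spread between libraries.

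Pik3cg was lower in p110g-/- macrophages in M-CSF and in IL-4. Its signal in M-CSF was 1966 ± 79.2 against 5210.4 ± 188 in WT, a log2 fold change of -1.41 (SE 0.23, adjusted p = 0.0027), and in IL-4 it was 1001 ± 71.2 against 3101 ± 166, a log2 fold change of -1.63 (SE 0.23, adjusted p = 0.00063). The libraries numbered 1 to 3 held 5307.5, 5330.3 and 4993.5 in WT M-CSF, 1887.5, 2045.8 and 1965.8 in p110g-/- M-CSF, 3068.2, 2952.9 and 3280.5 in WT IL-4, and 955.6, 1083.3 and 964.8 in p110g-/- IL-4. In IFNg/LPS the p110g-/- signal was 2379.5 ± 1178 against 2824 ± 654 in WT, and this difference did not pass the test (log2 fold change -0.34, adjusted p = 0.37). The library labelled p110g-/- IFNg/LPS, number 1, held 3691.4, above the 3 WT IFNg/LPS libraries (3559.5, 2309 and 2604.2), while numbers 2 and 3 held 1410.5 and 2036.7. With only the libraries numbered 2 and 3 the adjusted p in IFNg/LPS was 0.023, and without the p110g-/- library numbered 1 it was 0.0070, in a range of 0.0070 to 0.97 over the alternatives. Because RNA of the locus was still counted in p110g-/- cells and values are totals per gene, Pik3cg checks the genotype labels in part. In WT cells Pik3cg fell with IFNg/LPS (log2 fold change -0.91, adjusted p = 0.0026).

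**Figure D1:**
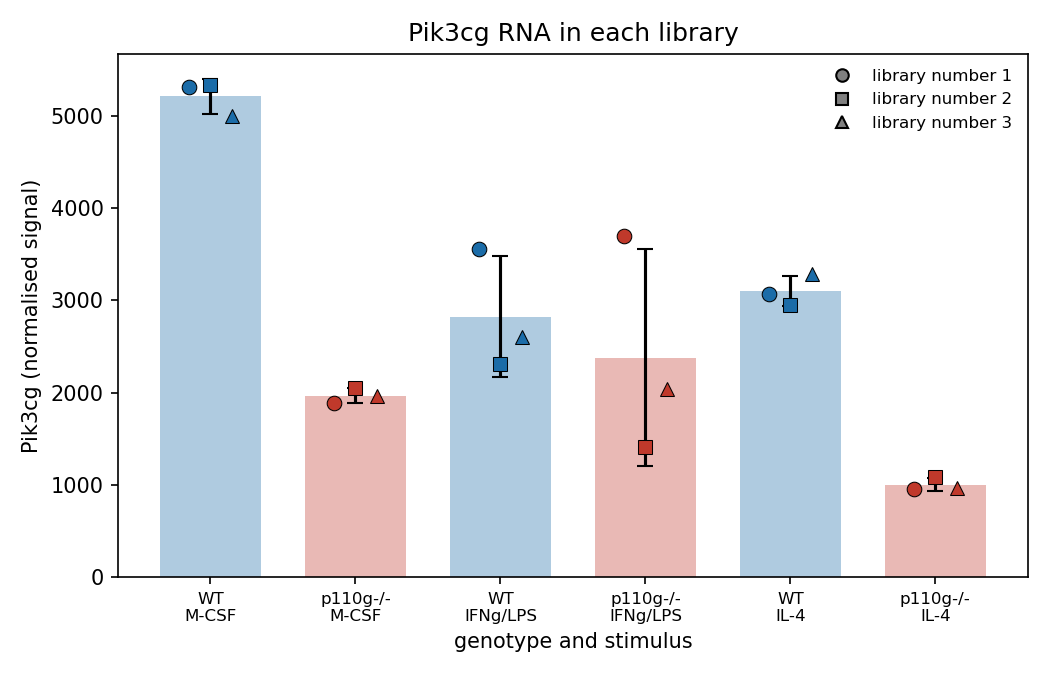
Pik3cg signal in each of the 18 libraries (y axis, normalised signal, linear from 0) by group (x axis), points marked by library number, bars at the mean with SD of 3 libraries. In M-CSF and IL-4 the p110g-/- libraries lie below all WT libraries, and in IFNg/LPS the p110g-/- library numbered 1 lies at 3691.4, above the WT libraries.

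Stimulus and genotype both separated the libraries. Over all tested genes the leading principal component held 73.6% of the variance and parted the IFNg/LPS libraries from the rest. The next component held 13.3% and parted IL-4 from M-CSF, and the component after it (3.08%) parted every p110g-/- library from every WT library. In each group the library numbered 1 stood apart from numbers 2 and 3. The squared difference between 2 libraries of a group, in units of its counting variance, was 39.3 to 149 where number 1 was involved and 14.5 to 46.8 between numbers 2 and 3.

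IFNg with LPS switched WT macrophages to inflammatory gene expression. Nos2, the inducible nitric oxide synthase, reached 221756 ± 43983 from 6.07 ± 2.08 in M-CSF, Cxcl9, a chemokine that draws T cells, reached 194503 ± 32639 from 44.0 ± 7.71, and Irg1, which makes itaconate, reached 392846 ± 69201 from 186 ± 55.0. Il12b, the p40 subunit of interleukin 12, rose by 7.51 on the log2 scale, Tnf by 4.70, and the anti-inflammatory cytokine Il10 by 4.52 (adjusted p = 6.2e-09, 4.2e-12 and 1.5e-05). Mrc1, the mannose receptor, fell (log2 fold change -5.71, adjusted p = 3.4e-12), as did Sesn1, a regulator of mTOR complex 1 (-5.36, adjusted p = 4.6e-14), and Pparg, a lipid-sensing nuclear receptor (-3.71, adjusted p = 2.5e-08). In all, 11538 of 15627 tested genes passed the test, 5676 higher and 5862 lower. In p110g-/- cells the count was 11408, with 5661 higher and 5747 lower.

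Whole gene groups moved together in this response. All 24 tested inflammatory cytokines and chemokines rose in WT (camera adjusted p = 3.1e-09), as did all 18 interferon gamma-induced GTPases and factors, led by Gbp2, Gbp5 and Gbp4, which attack vacuoles of intracellular pathogens (log2 fold changes 8.17, 8.48 and 10.37; camera adjusted p = 2.4e-10). All 27 type I interferon-stimulated genes, such as Cmpk2 (7.92), and all 20 NF-kB subunits and feedback genes, such as Icam1 (3.60), rose too (camera adjusted p = 4.7e-10 and 7.7e-08). Of the MHC class I presentation genes 17 of 19 rose and 1 fell (camera adjusted p = 1e-08), with the peptide transporter Tap2 at 3.49. With an estimated correlation the adjusted p of these 5 lists was 0.24, 0.24, 0.56, 0.32 and 0.24. Adjusted over the list alone, the counts were the same except for MHC class I (18 higher, 1 lower). The same lists rose in p110g-/- cells, with 24 of 24, 18 of 18, 27 of 27, 19 of 20 and 17 of 19 members higher (camera adjusted p from 1.1e-10 to 7.5e-08, and 0.22, 0.24, 0.47, 0.32 and 0.24 as adjusted p with an estimated correlation).

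Metabolic and growth genes moved as well in WT cells given IFNg/LPS. Of the glycolysis and hypoxia genes 21 of 24 rose and 1 fell, with the lactate transporter Slc16a3 at 4.57 and the glycolytic enzyme Pgk1 at 3.48 on the log2 scale. Of the oxidative stress genes 13 of 18 rose and 1 fell, led by the haem-degrading enzyme Hmox1 (3.85). Of the cell cycle genes 24 of 30 fell, such as the mitotic cyclin Ccnb2 (-4.94) and the spindle motor Kif11 (-3.62), while 3 rose, among them cyclin E1, Ccne1 (3.43). LXR targets and lipid genes fell in 12 of 20 members and rose in 2, with fatty acid synthase, Fasn, at -2.85, and complement and scavenger genes fell in 11 of 17 and rose in 3. Co-stimulatory Cd40 (7.19) and Cd86 (4.61) led 9 of 15 MHC class II and co-stimulation genes that rose. These 6 lists passed camera (adjusted p = 2.9e-08, 0.0016, 1.5e-05, 0.030, 0.044 and 0.027 in the order given). With an estimated correlation their adjusted p was 0.39, 0.66, 0.66, 0.56, 0.66 and 0.66. Adjusted over the list alone, the counts did not change. Sterol synthesis genes fell in 11 of 24 members and rose in 2, and the list reached an adjusted p of 0.055 by camera of 0.031 with the replicate number as a block, and adjusted p = 0.73 with an estimated correlation.

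IL-4 drove the alternative activation program in WT macrophages, 24 h later than the M-CSF libraries, so stimulus and time cannot be told apart here. Retnla, a secreted resistin-like protein, reached 219735 ± 61981, and the arginine-degrading enzyme Arg1 reached 5645 ± 2349, both at or under the floor in M-CSF. Chi3l3, a chitinase-like protein, reached 183944 ± 49466 from 3028 ± 3252 (log2 fold change 6.45, adjusted p = 7.4e-07), and the eosinophil chemokine Ccl24 rose by 6.48 (adjusted p = 7.8e-07). Without the WT M-CSF library numbered 1 the Chi3l3 value was 7.31. Of the alternative activation markers 24 of 26 rose and none fell, with the checkpoint ligand Pdcd1lg2 at 6.19 and the arginine transporter Slc7a2 at 5.14 (camera adjusted p = 1.8e-16, and adjusted p = 0.00066 with an estimated correlation). In p110g-/- cells 24 of 26 rose (camera adjusted p = 1.2e-17, and adjusted p = 0.00047 with an estimated correlation). In all, 6868 genes passed in WT, 3577 higher and 3291 lower, and 6855 in p110g-/- cells, 3540 higher and 3315 lower.

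Growth, lipid and protein folding genes rose with IL-4 in WT. Of the cell cycle genes 29 of 30 were higher, such as Ccne1 (1.86 on the log2 scale) and the replication helicase subunit Mcm3 (1.10), and of the sterol synthesis genes 22 of 24, such as Hmgcs1 (1.28) and Insig1 (1.08). Unfolded protein and stress response genes rose in 14 of 20 members and fell in 1, with the endoplasmic reticulum chaperones Sdf2l1 (1.62) and Hspa5 (0.92). MHC class II and co-stimulation genes rose in 10 of 15 and fell in 1, with their regulator Ciita at 2.82 and the invariant chain Cd74 at 2.29. The camera adjusted p of these 4 lists was 8.1e-08, 9.2e-09, 0.00022 and 0.0025, and with an estimated correlation the adjusted p was 0.43, 0.39, 0.092 and 0.43. Adjusted over the list alone, 23 sterol genes were higher and the other counts did not change. Osteoclast genes rose in 5 of 8 members and fell in 1, and handling stress and immediate early genes rose in 9 of 16 and fell in 1, with the same counts over the list alone (camera adjusted p = 0.024 and 0.026, and adjusted p = 0.43 and 0.30 with an estimated correlation).

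Interferon, NF-kB and resident macrophage genes fell with IL-4 in WT. Type I interferon-stimulated genes were lower in 22 of 27 members and higher in 1, with the antiviral synthetase Oas2 at -3.66 on the log2 scale. Interferon gamma-induced GTPases and factors fell in 13 of 18 and rose in 3, and the cytokine signalling inhibitor Socs1 reached 4.48. NF-kB subunits and feedback genes fell in 11 of 20 and rose in 1, among them Nfkbiz (-3.22) and Relb (-1.05). Macrophage identity genes fell in 10 of 14, among them the transcription factor Maf (-3.39), the antibody receptor Fcgr1 (-3.10) and the LPS co-receptor Cd14 (-2.72), and complement and scavenger genes fell in 10 of 17 and rose in 1, with the scavenger receptor Stab1 at -3.54. The fractalkine receptor Cx3cr1 had the most negative value among the genes named by rule (-6.30, adjusted p = 3.5e-09). The camera adjusted p of these 5 lists was 2.5e-06, 0.0021, 0.0012, 4.6e-06 and 0.00010, and with an estimated correlation the adjusted p was 0.50, 0.43, 0.43, 0.092 and 0.30. Adjusted over the list alone, the lower members numbered 25, 13, 12, 10 and 11. Of the inflammatory cytokines and chemokines 10 of 24 fell and 3 rose (camera adjusted p = 0.059, 0.037 with the replicate number as a block, and adjusted p = 0.55 with an estimated correlation).

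Under IFNg/LPS, p110g-/- macrophages held more RNA of the interleukin 12 subunit p40 and of tumour necrosis factor, and less of arginase 1 and interleukin 10, than WT macrophages. Il12b reached 22020.0 ± 8239 against 3716 ± 2623 in WT, a log2 fold change of 2.72 (SE 0.55, adjusted p = 0.0042), and Tnf reached 24368 ± 2647 against 13977 ± 1959 (log2 fold change 0.81, SE 0.18, adjusted p = 0.0072). Arg1 stood at 84.8 ± 16.2 against 554 ± 37.6 (-2.71, SE 0.45, adjusted p = 0.00099), and Il10 at 759 ± 709.7 against 2707 ± 1706 (-2.14, SE 0.66, adjusted p = 0.041). The mannose receptor Mrc1 was lower as well (-0.89, adjusted p = 0.011), and Ciita, the regulator of MHC class II genes, was higher (0.93, adjusted p = 0.015). Other mediators fixed for this comparison had large values that did not pass: Il12a was at 272 ± 269 against 52.8 ± 57.9 (log2 fold change 2.44, adjusted p = 0.055, and 0.015 with the replicate number as a block), Il1b at 148135 ± 97467 against 48569.9 ± 37658 (1.69, 0.060, and 0.042 with the block), and Il6 at 10798 ± 9004 against 3024 ± 3152 (2.02, 0.094). The block also brought Vegfa (adjusted p 0.088 to 0.029, log2 fold change 1.03) and H2-Ab1 (0.17 to 0.044, 0.61) past the threshold. Without the WT IFNg/LPS library numbered 1, Il12a (3.30, 0.010), Il1b (2.28, 0.012) and Il6 (2.84, 0.018) passed as higher (ranges 7.6e-05 to 0.19, 0.012 to 0.21 and 0.00015 to 0.28 over the alternatives). Nos2 (0.13, adjusted p = 0.91), Cxcl9 (-0.46, adjusted p = 0.44), Cxcl10 (-0.26, adjusted p = 0.82), Cd274 (-0.09, adjusted p = 0.87) and Tgfb1 (-0.07, adjusted p = 0.76) did not pass. The Il10 call ended without any 1 of the WT IFNg/LPS libraries (adjusted p 0.13, 0.060 and 0.060 for numbers 1 to 3), without the p110g-/- library numbered 2 (0.20, log2 fold change -1.42) or 3 (0.091), in DESeq2 (0.055), without trend and robust settings (0.057) and in a fit of the 6 libraries alone (0.16), in a range of 0.00079 to 0.20 over the alternatives, and without the p110g-/- library numbered 1 its value was -2.89. The Ciita call ended without the WT library numbered 3 (0.051) or the p110g-/- library numbered 2 (0.079), and in the 6-library fit Ciita and Mrc1 had an adjusted p of 0.075 and 0.057 (ranges 0.00080 to 0.079 and 0.00089 to 0.057).

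**Figure D2:**
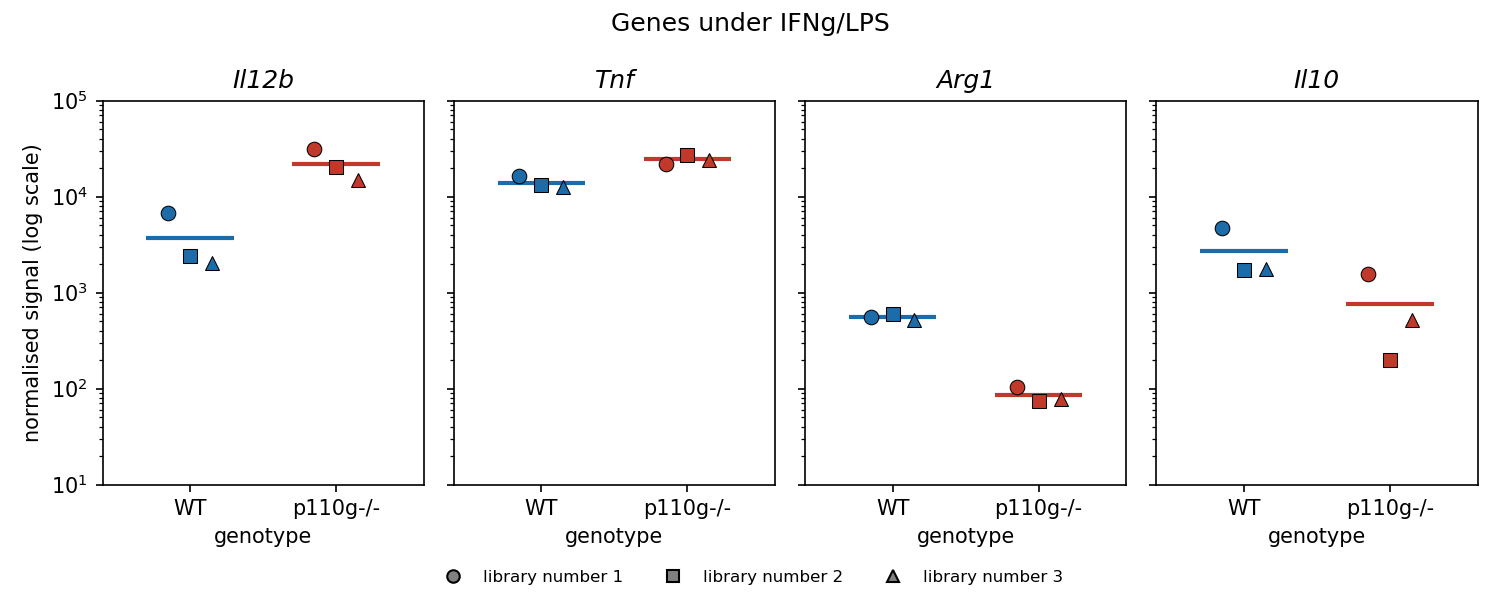
Signal of Il12b, Tnf, Arg1 and Il10 in the IFNg/LPS libraries (y axis, normalised signal, log scale) for WT and p110g-/- (x axis), points marked by library number, lines at the mean of 3 libraries. Il12b and Tnf lie higher and Arg1 lower in all p110g-/- libraries than in all WT libraries.

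Complement, scavenger and lysosome genes were lower in p110g-/- cells under IFNg/LPS by camera's preset test. Of the complement and scavenger genes 8 of 17 fell and none rose, 11 adjusted over the list alone, with the chemokine Pf4 at -1.69 on the log2 scale, the complement receptor C3ar1 at -0.55 and properdin, Cfp, at -1.03 (camera adjusted p = 0.00012, and adjusted p = 0.51 with an estimated correlation). Of the lysosome and phagocytosis genes 9 of 30 fell and none rose, 12 adjusted over the list alone, among them the protease legumain, Lgmn (-0.96), and progranulin, Grn (-0.78; camera adjusted p = 0.00028, and adjusted p = 0.83 with an estimated correlation). Macrophage identity genes fell in 8 of 14 members and rose in 2, 10 and 2 adjusted over the list alone (camera adjusted p = 0.027, and adjusted p = 0.81 with an estimated correlation). The LPS co-receptor Cd14, a member of this list, rose from 23203 ± 5341 in WT to 87034 ± 12938 (1.92, adjusted p = 0.00017). Stress response genes fell in 5 of 20 members, also adjusted over the list alone, such as Ddit3 (-0.78; camera adjusted p = 0.017, and adjusted p = 0.51 with an estimated correlation). Glycolysis and hypoxia genes passed camera as higher (0.017, and adjusted p = 0.83 with an estimated correlation), with 2 of 24 members past the test in both counts, among them hexokinase 2, Hk2 (0.80). LXR targets and lipid genes did not pass as a list (camera adjusted p = 0.088, 0.044 with the libraries numbered 2 and 3 only, and adjusted p = 0.83 with an estimated correlation), but 7 of 20 members fell and 1 rose (7 and 2 adjusted over the list alone), with the lipid droplet protein Plin2 at -1.30 and Pparg at -2.04. The MHC class II list had a camera adjusted p of 0.057, of 0.030 with the replicate number as a block, of 0.0033 with the libraries numbered 2 and 3 only, and adjusted p = 0.83 with an estimated correlation. It held 2 of 15 members higher, 2 over the list alone and 3 with the block. With the block the lower members numbered 12 complement and scavenger, 12 lysosome and 6 stress response genes. In the fit of the 6 IFNg/LPS libraries alone the Pparg call ended (adjusted p = 0.054, range 7.8e-11 to 0.054 over the alternatives).

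The inflammatory list did not pass the test between genotypes under IFNg/LPS, with 2 of 24 members higher and 3 lower (4 and 3 over the list alone; camera adjusted p = 0.41). The immune suppressive and tissue repair list held 2 higher and 6 lower of 23 (3 and 6 over the list alone; adjusted p = 0.32), with the collagenase Mmp13 at -1.44 (adjusted p = 0.0016) and thrombospondin 1, Thbs1, at 1.31 (adjusted p = 0.0017). Alternative activation markers held 2 higher and 2 lower of 26 (2 and 3 over the list alone; adjusted p = 0.68). No type I interferon-stimulated gene of 27, no interferon gamma-induced GTPase or factor of 18 and no MHC class I gene of 19 passed by limma over all genes or over the list alone (camera adjusted p = 0.31, 0.30 and 0.32), while 2 MHC class I genes were lower with the block. Members past the test numbered 1 lower of 20 NF-kB genes, 1 higher and 1 lower of 27 PI3K pathway genes, 1 lower of 30 cell cycle genes, 1 higher and 1 lower of 24 sterol synthesis genes, 2 higher and 1 lower of 18 oxidative stress genes, and 3 higher and 5 lower of 22 chemokine receptor, integrin and migration genes (camera adjusted p = 0.28, 0.41, 0.33, 0.32, 0.58 and 0.81). Adjusted over the list alone these counts were 0 lower, 0 higher and 1 lower, 1 lower, 1 higher and 1 lower, 2 higher and 2 lower, and 3 higher and 5 lower. With the block the higher and lower members numbered 3 and 1, 2 and 2, 1 and 1, 4 and 1, 3 and 2, and 3 and 6 in the same order, and 5 and 3 inflammatory, 3 and 7 immune suppressive and 3 and 4 alternative activation genes. With the libraries numbered 2 and 3 only the NF-kB list passed as higher (0.014, and adjusted p = 0.83 with an estimated correlation over all libraries). Stard4, an intracellular sterol carrier, rose from 109.8 ± 3.41 to 543 ± 36.5 (2.29, adjusted p = 8.9e-08), and the cystine transporter Slc7a11 rose (0.87, adjusted p = 0.0043). No gene of the 16 handling stress and immediate early genes passed over all genes, against 3 higher and 5 lower over the list alone and 3 lower with the block (camera adjusted p = 0.53). Among markers of other cell types, mast cell and basophil genes fell in 2 of 6 members in either count (camera adjusted p = 0.045, adjusted p = 0.81 with an estimated correlation, and 0.072 with the libraries numbered 2 and 3 only). Their median log2 value was 3.61 to 3.84 in WT and 1.93 to 3.14 in p110g-/- IFNg/LPS libraries, so members at the lower level lay near the floor. Neutrophil, dendritic cell, B cell, T and NK cell, fibroblast and osteoclast lists did not pass (camera adjusted p = 0.32, 0.41, 0.32, 0.68, 0.50 and 0.47). With the libraries numbered 2 and 3 only the neutrophil list passed as lower (0.029, and adjusted p = 0.83 with an estimated correlation over all libraries), with 3 of 15 members lower, as with the block.

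The largest genotype differences under IFNg/LPS lay in genes of varied function. Cysltr2, a receptor for cysteinyl leukotrienes, stood at 12.0 ± 4.06 against 1249 ± 449 in WT (-6.58, SE 0.29, adjusted p = 2e-09), and Plekhg1, a protein with a pleckstrin homology domain, at 69.9 ± 7.72 against 1811 ± 116 (-4.68, SE 0.30, adjusted p = 8.2e-08). The stress cytokine Gdf15 (-3.44, adjusted p = 0.00042), endothelial lipase, Lipg (-3.54, adjusted p = 0.0034), the histone deacetylase Hdac9, 8 tested genes from Pik3cg in gene order (-3.38, adjusted p = 6.5e-05), and the monoamine transporter Slc18a1 (-3.24, adjusted p = 6.3e-07) were lower too. H60a, a ligand of the natural killer receptor NKG2D, was at 2686 ± 218 against 137 ± 6.47 (4.28, SE 0.10, adjusted p = 3e-13). The phosphoinositide phosphatase Inpp4b (3.18, adjusted p = 5.7e-05), the calcium channel subunit Cacna1a (2.87, adjusted p = 7.3e-06), the calcium sensor Hpca (3.33, adjusted p = 6.5e-05) and Ccr7, a receptor that guides cells to lymph nodes (2.79, adjusted p = 0.0039), were higher. Of these genes, Cysltr2, Plekhg1, Gdf15, Hdac9, H60a, Cacna1a and Hpca changed in the same direction under all 3 stimuli. Cysltr2, Gdf15 and Cacna1a lay near other such genes on their chromosomes. In all, 2303 of 15627 genes passed the test, 1085 higher and 1218 lower in p110g-/- cells. With the replicate number as a block 2974 passed, 1453 higher and 1521 lower. The count was 1466 without the p110g-/- library numbered 2, 708 in the fit of the 6 libraries alone, and 4166 with the libraries numbered 2 and 3 only. In the 6-library fit the Ccr7 call ended (adjusted p = 0.051, range 8.6e-06 to 0.051 over the alternatives), and without the WT library numbered 1 its value was 3.44.

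**Figure D3:**
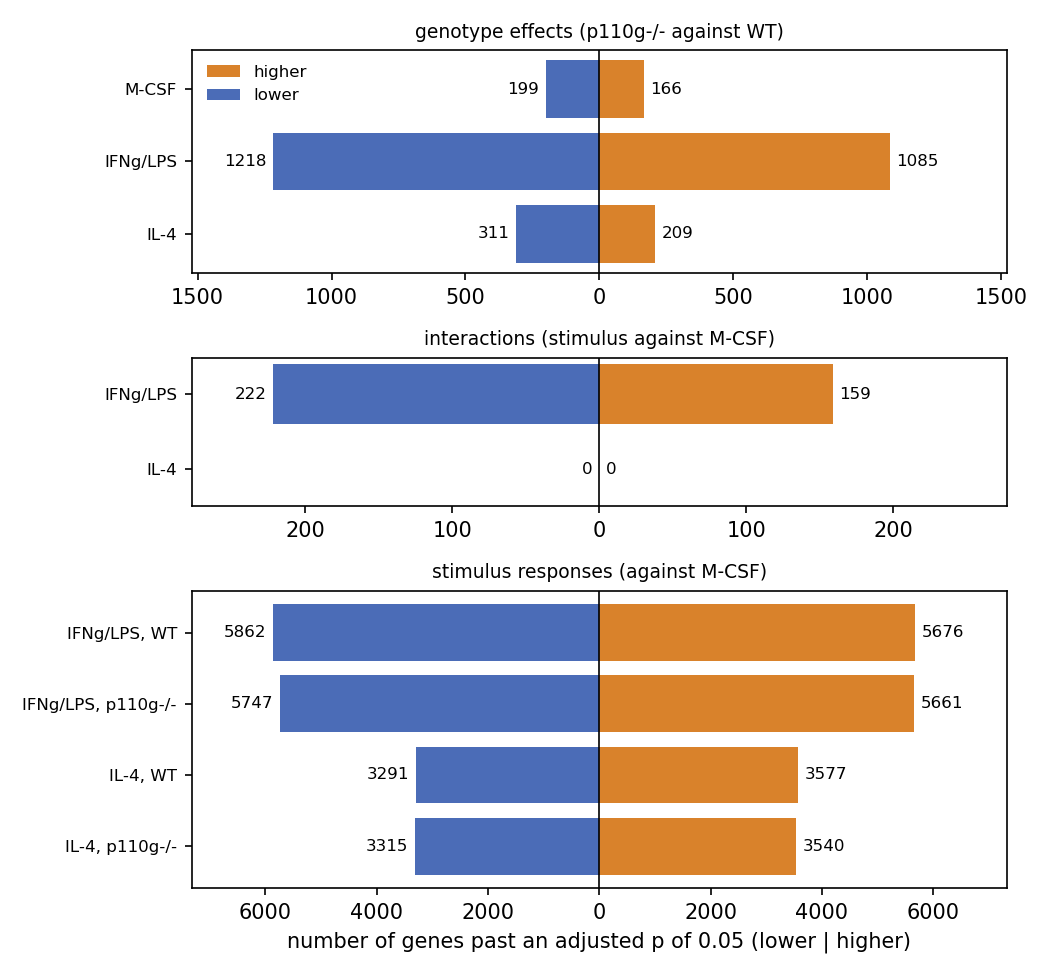
Number of genes past an adjusted p of 0.05 in each comparison (x axis, number of genes, linear from 0), higher to the right and lower to the left of 0, for the 3 genotype effects, the interactions and the stimulus responses in separate panels. The IFNg/LPS genotype effect holds 1085 higher and 1218 lower genes, and the interaction for IL-4 holds none.

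In M-CSF alone p110g-/- macrophages differed from WT in a smaller number of genes. H60a stood at 3473 ± 269 against 62.8 ± 1.06 in WT (5.76, SE 0.10, adjusted p = 3.3e-15), and Best1, a chloride channel, at 929.8 ± 139 against 243 ± 59.6 (1.95, adjusted p = 0.00017). Cyp4f18, a fatty acid hydroxylase that acts on leukotriene B4, was at 20.1 ± 6.06 against 833 ± 87.5 (-5.34, SE 0.26, adjusted p = 5.7e-09), Plekhg1 at 29.6 ± 14.7 against 639 ± 61.0 (-4.53, adjusted p = 1.8e-07), and the lysophosphatidic acid receptor Lpar2 at 9.33 ± 3.90 against 85.6 ± 6.75 (-3.13, adjusted p = 5.3e-05). Hddc3 (2.51), Hpca (3.99) and Cdo1, a cysteine-degrading enzyme (3.06), were higher, and Etohi1 (-2.77), Erdr1 (-2.78) and Gdf15 (-2.84) lower. Lrig3 was at the floor in p110g-/- cells, 3.17 ± 1.83 against 58.2 ± 2.68 in WT. Of the complement and scavenger genes 2 of 17 fell, 4 adjusted over the list alone, Pf4 (-2.13, adjusted p = 2.2e-05) and Stab1 (-0.73, adjusted p = 0.0080) (camera adjusted p = 0.00017, and adjusted p = 0.47 with an estimated correlation). Cell cycle genes were lower as a list, with a median log2 fold change of -0.74 over 30 members and values of -1.05 for the survivin gene Birc5 and -1.09 for Ccnb2. By limma none of them passed over all genes and 22 were lower adjusted over the list alone (camera adjusted p = 4.9e-14, and adjusted p = 0.47 with an estimated correlation). The median log2 value of the list was 9.972, 9.995 and 9.305 in the WT M-CSF libraries numbered 1 to 3. In p110g-/- M-CSF it was 8.588, 9.307 and 9.336, so WT number 3 lay at the level of p110g-/- numbers 2 and 3. Without the WT M-CSF library numbered 3, Birc5 and Ccnb2 passed as lower (adjusted p = 0.014 and 0.018, ranges 0.0037 to 0.21 and 0.0081 to 0.27 over the alternatives).

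Interferon genes were lower as lists in M-CSF by camera's preset test. Type I interferon-stimulated genes had a median log2 fold change of -0.71 over 27 members, none past the test over all genes or over the list alone, with Rsad2, an antiviral enzyme, at -1.52 (adjusted p = 0.14; camera adjusted p = 3.8e-06, and adjusted p = 0.92 with an estimated correlation). Interferon gamma-induced GTPases and factors had a median of -0.40, with 1 of 18 lower and 2 over the list alone (camera adjusted p = 0.0023, and adjusted p = 0.92 with an estimated correlation). With the libraries numbered 2 and 3 only the GTPase list did not pass (0.37). The WT M-CSF library numbered 1 had the highest median log2 value of the type I genes, 11.9 against 10.6 and 10.5 in numbers 2 and 3, and the p110g-/- libraries had 10.9, 9.36 and 10.7. The member past the test was Iigp1, a GTPase acting on vacuoles of pathogens (-1.95, adjusted p = 0.00097). Stard4 rose (1.01, adjusted p = 0.00093). Markers of other cell types moved beside these groups: fibroblast and stroma genes were higher, with a median of 1.38 over 12 members and 1 past the test (2 over the list alone), and mast cell and basophil genes had a median of -1.05 over 6 members with none past the test and 3 over the list alone. Camera gave these lists an adjusted p of 4.8e-06 and 0.0016, and adjusted p = 0.47 and 0.47 with an estimated correlation. With the libraries numbered 2 and 3 only both passed camera (adjusted p = 1.1e-10 and 0.0056), with 7 of 12 fibroblast and stroma genes higher. In all, 365 of 15627 genes passed, 166 higher and 199 lower in p110g-/- cells. The count was 241 without the p110g-/- library numbered 1, 239 without number 2, 688 with the libraries numbered 2 and 3 only, 673 in DESeq2 and 860 with library weights. In the fit of the 6 M-CSF libraries alone the calls of Gdf15 and Stard4 ended (adjusted p = 0.062 and 0.090, ranges 5.3e-06 to 0.062 and 4e-07 to 0.090 over the alternatives).

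In IL-4, few markers of alternative activation passed the test between the genotypes. Arg1 (-0.35 on the log2 scale, adjusted p = 0.81), Retnla (1.24, 0.70), Chi3l3 (0.95, 0.52), Mrc1 (0.41, 0.41) and Ccl24 (1.88, 0.12) did not pass the test. Without the p110g-/- IL-4 library numbered 1, Ccl24 passed as higher (2.60, adjusted p = 0.014, range 0.0017 to 0.43 over the alternatives). As a list the alternative activation markers were higher by camera's preset test, with a median of 0.41 and 1 of 26 members past the test over all genes and over the list alone (camera adjusted p = 0.0020, and adjusted p = 0.23 with an estimated correlation). The list also passed as higher by fry (adjusted p = 0.020) and by camera with the libraries numbered 2 and 3 only (adjusted p = 0.0014). Inflammatory cytokines and chemokines were lower, with a median of -0.38 (camera adjusted p = 0.0020, and adjusted p = 0.55 with an estimated correlation). The median log2 value of this list was 2.65 to 3.88 over the IL-4 libraries, so members at that level lay near the floor. Tnf alone, 1 member of 24, passed the test (5 over the list alone), at 136 ± 17.4 against 250.1 ± 46.3 in WT (-0.87, SE 0.18, adjusted p = 0.013). Immune suppressive and tissue repair factors fell in 5 of 23 members and rose in 1 (7 and 1 over the list alone), led by the interleukin 1 receptor antagonist Il1rn (-1.99, adjusted p = 0.00044) and Mmp13 (-1.46, adjusted p = 0.0037; camera adjusted p = 0.021, adjusted p = 0.27 with an estimated correlation, and 0.24 with the libraries numbered 2 and 3 only). MHC class II genes were higher as a list, with a median of 0.50, none of 15 past limma's test over all genes and 8 over the list alone (camera adjusted p = 0.0023, and adjusted p = 0.55 with an estimated correlation). The Tnf call ended without the WT IL-4 library numbered 2 (0.082) or 3 (0.061) and without the p110g-/- library numbered 2 (0.056) or 3 (0.083), in a range of 4.8e-05 to 0.083 over the alternatives.

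Some scavenger and chemotactic receptor genes were lower in p110g-/- macrophages in IL-4. Stab1 fell (-1.61, SE 0.14, adjusted p = 3.1e-06), as did Pf4 (-1.55, adjusted p = 0.00051) and the complement receptor C5ar1 (-0.97, adjusted p = 0.0037), 3 of 17 complement and scavenger genes and 4 over the list alone (camera adjusted p = 0.041, and adjusted p = 0.72 with an estimated correlation). Chemokine receptors, integrins and migration genes fell in 3 of 22 (6 over the list alone; camera adjusted p = 0.0092, and adjusted p = 0.23 with an estimated correlation). With the libraries numbered 2 and 3 only neither list passed (adjusted p = 0.79 and 0.17), with 3 higher and 5 lower and with 2 higher and 7 lower members. Type I interferon-stimulated genes (median -0.60, none of 27 past the test in either count), glycolysis and hypoxia genes (median -0.20, 1 of 24 lower in either count) and oxidative stress genes (median -0.24, 2 of 18 lower in either count, with the peroxidase Prdx1 at -0.97) were lower as lists. Their camera adjusted p was 0.0016, 0.0027 and 0.0071, and the adjusted p was 0.82, 0.81 and 0.82 with an estimated correlation. The WT IL-4 library numbered 1 had the highest median log2 value of the type I genes, 10.02 against 8.89 and 8.70 in numbers 2 and 3. The p110g-/- IL-4 libraries had 8.59, 8.34 and 8.61. With the libraries numbered 2 and 3 only the type I list still passed camera (adjusted p = 0.0175). Mast cell and basophil genes were lower beside these groups, with a median of -1.61 and 3 of 6 past the test (5 over the list alone), and fibroblast and stroma genes were higher, with a median of 1.05, none of 12 past the test and 1 over the list alone. These lists had a camera adjusted p of 2.8e-05 and 0.0016, and adjusted p = 0.22 and 0.55 with an estimated correlation. With the libraries numbered 2 and 3 only both passed camera (adjusted p = 0.021 and 3.9e-05). In that fit 3 of 6 mast cell and basophil genes were lower and 7 of 12 fibroblast and stroma genes higher. H60a was at 4050.2 ± 289 against 87.9 ± 12.5 (5.52, adjusted p = 6.3e-15), Cyp4f18 at 43.6 ± 8.49 against 1821 ± 91.1 (-5.37, adjusted p = 5.1e-09), and Cysltr2 at 17.9 ± 4.76 against 105 ± 10.1 (-2.52, adjusted p = 7.2e-05). In all, 520 of 15627 genes passed, 209 higher and 311 lower in p110g-/- cells. The count was 276 and 239 without the WT library numbered 2 or 3, 252 and 247 without the p110g-/- library numbered 2 or 3, 2285 with the libraries numbered 2 and 3 only, 921 in DESeq2 and 3039 with library weights. The Prdx1 call ended without the p110g-/- library numbered 3 (0.052, range 4.8e-06 to 0.052), and the C5ar1 call in the 6-library fit (0.055, range 9.5e-06 to 0.055).

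**Figure D4:**
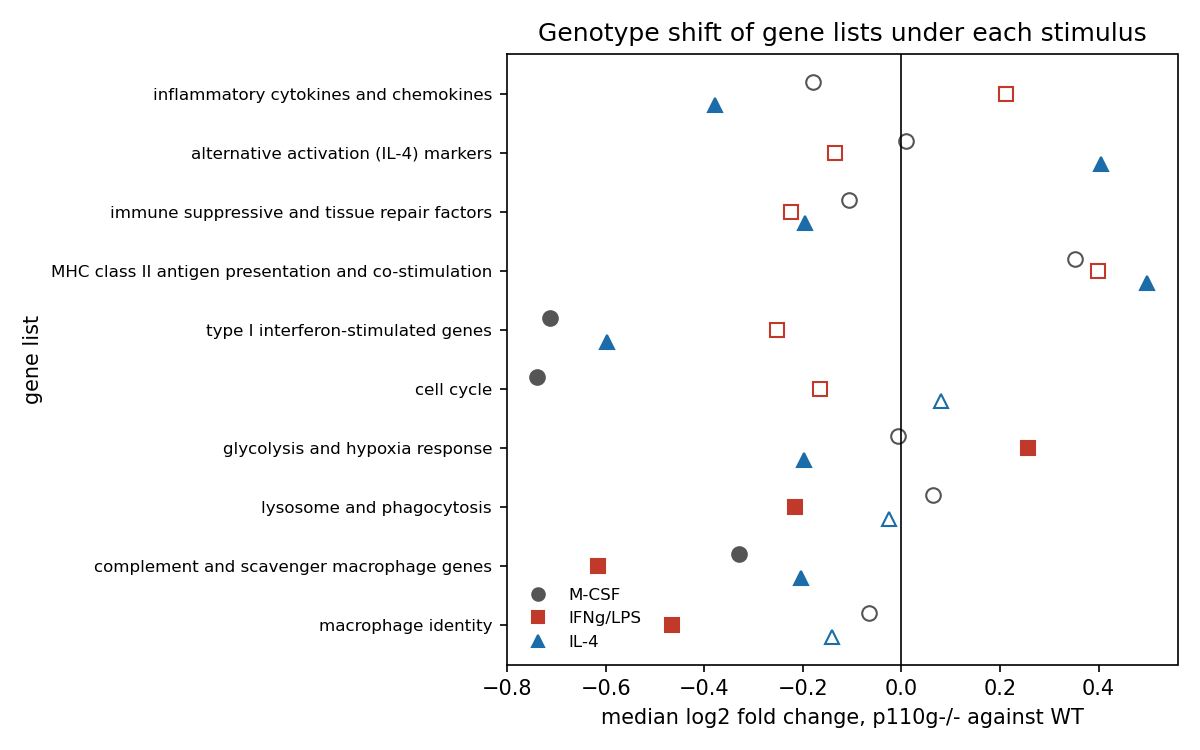
Median log2 fold change of p110g-/- against WT (x axis) over the tested members of 10 fixed gene lists (y axis), 1 marker per stimulus, filled where camera gave an adjusted p under 0.05 with its preset correlation. With an estimated correlation none of these genotype shifts passed.

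The genotype effect itself differed between IFNg/LPS and M-CSF for part of the genes. Inpp4b changed by 4.28 more on the log2 scale in IFNg/LPS than in M-CSF, and Cysltr2 by -4.46 (adjusted p = 0.00070 and 3.3e-05). Differences passed for Cd14 (2.21, adjusted p = 0.0049), Stard4 (1.29, adjusted p = 0.0051), Herpud1, an endoplasmic reticulum stress gene (-1.06, adjusted p = 0.0089), Rgl1 (-2.17, adjusted p = 3.6e-06), Csrp1 (-2.76, adjusted p = 7.3e-06), Ktn1 (2.30, adjusted p = 3.6e-06) and H60a (-1.49, adjusted p = 3.4e-05). The Il12b difference was 3.13 (adjusted p = 0.048), while Tnf (0.79, adjusted p = 0.12) and Il10 (0.19, adjusted p = 0.95) did not pass, so their genotype effects were not shown to differ between IFNg/LPS and M-CSF. Tnf passed as higher in p110g-/- cells in IFNg/LPS and as lower in IL-4, and the difference between these effects was not tested. Arg1 was at or under the floor in M-CSF in both genotypes, so its difference was not estimated. In all, 381 of 15627 genes passed, 159 with a positive and 222 with a negative difference. For IL-4 none passed by limma in the main fit, with 1156 genes at an unadjusted p under 0.05. None passed in edgeR, against 77 in DESeq2, 403 with library weights and 385 with the libraries numbered 2 and 3 only. As lists, lysosome and phagocytosis genes had a median difference of -0.36 with 1 of 30 members past the test, and cell cycle genes of 0.59 with 1 of 30. Over the list alone these were 5 and 3. Glycolysis and hypoxia genes (0.27, none of 24 in either count) and fibroblast genes (-0.94, none of 12, and 1 lower over the list alone) passed camera too. The camera adjusted p of these 4 lists was 9.6e-06, 0.00017, 0.040 and 0.046, and each had an adjusted p of 1.0 with an estimated correlation. With the libraries numbered 2 and 3 only the cell cycle list did not pass (0.19). For IL-4 the cell cycle list had a median difference of 0.82, alternative activation markers of 0.54 and inflammatory cytokines and chemokines of -0.54, no member past limma's test over all genes, and 5, 2 and 0 over the list alone (camera adjusted p = 1.3e-13, 0.0078 and 0.042, and adjusted p = 0.53, 0.53 and 0.72 with an estimated correlation). With the libraries numbered 2 and 3 only the inflammatory list did not pass in this interaction (0.14).

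Single libraries moved the interaction results. The Il12b call ended in edgeR (0.15), with an added constant of 0.5 (0.060), without trend and robust settings (0.069), in the fit of the groups compared (0.094), and without any of the 12 libraries except the WT IFNg/LPS and the p110g-/- M-CSF library numbered 1 (0.051 to 0.12), in a range of 0.0048 to 0.15 over the alternatives. Without the p110g-/- M-CSF library numbered 1 the Il12b difference was 3.74 and the Tnf difference passed (0.049, range 0.0038 to 0.24). The IFNg/LPS interaction count was 633 without the WT IFNg/LPS library numbered 1 and 212 without number 2, 190 and 206 without the WT M-CSF libraries numbered 2 and 3, 183 and 202 without the p110g-/- M-CSF libraries numbered 2 and 3, and 211 without the p110g-/- IFNg/LPS library numbered 2. It was 892 in DESeq2, 211 in the fit of the groups compared and 1708 with the libraries numbered 2 and 3 only, and the IL-4 interaction count was 89 without the p110g-/- IL-4 library numbered 1.

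A common set of genes changed with genotype under every stimulus. Of the genes called, 148 passed in the same direction in all 3 genotype effects, 46 higher and 102 lower, among them H60a, Hpca, Hddc3, Plekhg1, Etohi1, Erdr1 and Gdf15. M-CSF and IFNg/LPS shared 73 higher and 129 lower genes, against 11.5 and 15.5 for independent lists, and 6 genes went opposite ways. M-CSF and IL-4 shared 79 higher and 128 lower genes, against 2.22 and 3.96, with 1 opposite. IFNg/LPS and IL-4 shared 74 higher and 137 lower genes, against 14.5 and 24.2, with 22 opposite. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.358, 0.501 and 0.295 for these pairs. The 3 genotype effects share no library. The deviations of same-numbered M-CSF and IL-4 libraries correlated within WT and within p110g-/-, so the effects can share deviations that go with the number, which the counts for independent lists do not allow for. Genes called higher or lower by IFNg/LPS in WT did not pass as sets with genotype in IL-4 (adjusted p = 0.37 and 0.60), nor did genes called by IL-4 in WT with genotype in IFNg/LPS (0.37 and 0.21).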

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

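The count ratios between IFNg/LPS and M-CSF, the test of the Pik3cg interaction and the tests on regrouped libraries were chosen only after the result was seen, and the other tests before.

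The 148 genes that changed the same way with genotype under all 3 stimuli lay close together on the chromosomes. In the gene order of GRCm38.p6, 91 of the 134 genes that could be placed had another gene of the set within 10 tested genes, against a median of 22 and at most 45 in 10000 random sets matched on mean value, which is consistent with stretches of DNA from another mouse strain kept in the p110g-/- line. Genes in unnamed or zinc finger families made up 30.6% of the set, a share at which the test fixed beforehand cannot tell whether reads shared between near-identical copies explain it, and without them 53 of 93 still had a neighbour (at most 31 in random sets). DNA beside the targeted Pik3cg locus was contradicted as the cause of most of the set, because 7 of the placed genes lay within 100 tested genes of it (median 2 in random sets, at most 10). For those 7, which include Hdac9 at 8 tested genes, it stays open. The 43 placed genes without a neighbour in the set leave open an action of p110gamma on unlinked genes.

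More genes passed between the genotypes in IFNg/LPS than in M-CSF, by a ratio of 6.31. The ratio was 4.86 with quantile normalization and 6.06 with the libraries numbered 2 and 3 only, which argues against the normalization and the libraries numbered 1 as the whole cause. It fell to 2.31 with only the groups compared in each fit, above the bound of 1.5 set after the counts were seen, so unequal spread between the stimuli was not the whole cause by that bound, while part of the excess went with that change, so unequal spread stays open as part of the cause. The slope of the interaction on the mean response across 12810 genes was 0.0150, within the bound of 0.05 from 0 fixed beforehand. With each library left out it lay between -0.0124 and 0.0486. The value of 0.0486, close to the bound, came without the WT IFNg/LPS library numbered 1. By that bound a weaker or stronger IFNg/LPS response as a whole was contradicted.

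The library labelled p110g-/- IFNg/LPS, number 1, held Pik3cg at 3691.4, above the WT libraries. A wrong genotype label was contradicted, because over the 206 genes other than Pik3cg called the same way in M-CSF and IL-4 its score was 0.985, where WT IFNg/LPS libraries scored 0.0155 to 0.0343 and the other p110g-/- libraries 1.01 and 0.945. A share of WT RNA was contradicted, because the Pik3cg value would need a share of 1.79. An effect of IFNg/LPS on RNA from the rest of the locus stays open for the group (interaction adjusted p = 0.10). Numbers 2 and 3 of the group, under the same stimulus, held 1410.5 and 2036.7, so such an effect alone leaves number 1 unexplained. In WT IFNg/LPS number 1 was also the highest, at 3559.5 against 2309 and 2604.2. A cause that goes with the number was not tested.

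Regrouping the libraries at random did not serve as a test for single comparisons, because 3 libraries against 3 allow 10 splits and the real grouping alone is 1 of 10. The real grouping called 365 genes in M-CSF, 2303 in IFNg/LPS and 520 in IL-4 between genotypes, against at most 2, 460 and 0 in another split, and 11538, 11408, 6868 and 6855 in the responses to IFNg/LPS in WT and p110g-/- and to IL-4 in WT and p110g-/-, against 0 in each. For the IFNg/LPS interaction 6 of 100 groupings, the real one included, called at least 381 genes (at most 887). The 5 others kept the IFNg/LPS genotype groups whole, with the names swapped in 4, and exchanged libraries between the genotypes within M-CSF. Because they kept the genotype effect in IFNg/LPS, the regrouping could not decide whether chance gave this count. Groupings that exchanged libraries between the genotypes within IFNg/LPS called at most 158 genes. For the IL-4 interaction the real grouping called 0 genes, which all 100 groupings reached, with at most 919. The grouping with 919 moved no library out of its genotype group and swapped the genotype names in IL-4 alone. It therefore added the genotype effects of IL-4 and M-CSF and does not speak to chance.

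By limma the genotype effect differed between IFNg/LPS and M-CSF in 381 genes, a count for which the regrouping could not decide on chance. Genes named for the smallest adjusted p of each direction were Rgl1 (-2.17 on the log2 scale), Csrp1 (-2.76), Cysltr2 (-4.46), H60a (-1.49), B4galt5 (-0.85), Fam32a (1.09), Ktn1 (2.30), Apbb3 (1.85), Denr (0.69) and Inpp4b (4.28). Of the genes named for other reasons, Il12b (3.13), Cd14 (2.21), Stard4 (1.29) and Herpud1 (-1.06) differed too. The Il12b call ended in 14 of 27 alternatives, and those of Cd14, Stard4 and Herpud1 in none. Lists with a median difference past camera's preset test were cell cycle (0.59), glycolysis (0.27), lysosome (-0.36) and fibroblast genes (-0.94). For IL-4 they were inflammatory cytokines and chemokines (-0.54), alternative activation (0.54), immune suppressive (-0.37), interferon gamma-induced GTPases (0.30), cell cycle (0.82), glycolysis (-0.17), sterol synthesis (-0.32) and oxidative stress genes (-0.33). None of these lists passed with an estimated correlation, and no cause was tested.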

How the results depend on the processing

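The fits of the libraries numbered 2 and 3 only and edgeR with the replicate block were chosen only after the result was seen. Responses to stimuli kept their counts within 1.5 times in every setting. Of 142 gene results in the text 121 passed, 110 of these passed in every setting, and no called result changed sign. The cause of a moved value was not tested unless stated.

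Genes called between the genotypes in M-CSF numbered 365, and 688 with the libraries numbered 2 and 3, 639 in edgeR with the block, 673 in DESeq2, 860 with library weights and 239 to 336 with 1 library left out. In IFNg/LPS they numbered 2303, and 4166 with numbers 2 and 3, 708 with only the groups compared and 1466 to 2728 with 1 left out. Fewer libraries estimate the spread of every comparison when only the groups compared are fitted. That setting left 307 genes in M-CSF and 422 in IL-4, so the fall was largest in IFNg/LPS. In IL-4 the genes called numbered 520, and 2285 with numbers 2 and 3. They numbered 841 in edgeR with the block, 921 in DESeq2, 3039 with weights and 239 to 727 with 1 left out. The IFNg/LPS interaction held 381, and 1708, 673 in edgeR with the block, 892 in DESeq2, 1422 with weights, 211 with only the groups compared and 183 to 633 with 1 left out. The IL-4 interaction held 0, and 385, 9 with a constant of 8, 13 in edgeR with the block, 77 in DESeq2, 2 without trend and robust settings, 403 with weights and 0 to 89 with 1 left out. Weights were estimated gene by gene because the default method did not converge, and were 0.245 to 0.620 for the libraries numbered 1 and 0.644 to 2.82 for the others. At a threshold of 0.01 the pairs of genotype effects shared 120, 134 and 117 genes in 1 direction, against 202, 207 and 211, and with numbers 2 and 3 only 229 genes, not 148, went the same way in all 3. The immune suppressive list in the IL-4 response of WT was lower by camera (adjusted p = 0.86) and higher by fry (0.0067).

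Where the numbers did not pass the pairing check, the replicate block moved the genotype count from 365 to 555 in M-CSF and from 520 to 763 in IL-4. It moved the count from 381 to 716 in the IFNg/LPS interaction and from 0 to 8 in the IL-4 interaction (8 with genotype and number as the block). As a hint from the data, 15 of 18 libraries correlated best with a library of their own number (-0.00494 to 0.546 for same numbers, at most 0.265 for others). With the block Birc5, Ccnb2 and Rsad2 passed in M-CSF (adjusted p 0.023, 0.041 and 0.020), and it changed the call of no other gene named in the text than those and the ones the report gives. The block also moved member counts and calls of lists. By camera, MHC class II genes passed as higher in the M-CSF genotype effect (adjusted p 0.099 to 0.046). Sterol synthesis genes passed as lower in the IL-4 genotype effect (0.078 to 0.023).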

Other observations

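The listing of gene runs along chromosomes was chosen only after the result was seen, while the list tests were fixed before.

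Under IFNg/LPS, p110g-/- macrophages had lower Arg1, Pf4, Cfp, Lgmn and Plin2 and higher Il12b, Tnf, Cd14, Ccr7 and Hk2 than WT, while no interferon-stimulated gene of the list, Nos2 or Cxcl9 passed the test. These genes do not stand for their lists. The inflammatory list held 2 members higher and 3 lower of 24, and alternative activation markers 2 higher and 2 lower of 26. Neither list passed camera (adjusted p = 0.41 and 0.68). Pf4 was lower under all 3 stimuli, and the Tnf effect was not shown to differ from that in M-CSF, where Arg1 was at or under the floor in both genotypes. Il10 was lower too, but its call ended in 8 of 20 alternatives, and that of Ccr7 in 1. Stard4 rose in the same cells by 2.29 on the log2 scale, and Inpp4b, which removes a phosphate from a lipid product of PI3K, by 3.18. Inpp4b was not in the set shared by all 3 genotype effects, so its neighbours on the chromosome were not examined.

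The genes shared by all 3 genotype effects form runs along the chromosomes. The longest is a run of 25 genes on chromosome 2, all lower in p110g-/- cells, which holds Etohi1 among mostly unnamed genes, and a run of 6 on chromosome 14 holds Phyhip, Sorbs3 and Cysltr2. Chromosome 8 holds 23 genes of the set where 6.97 were expected, among them Cyp4f18, Lpar2, Gdf15 and Cacna1a. Since 91 placed genes of the set have such a neighbour, their differences may belong to the DNA around them and not to the loss of p110gamma, which these data cannot decide for Cysltr2, Cyp4f18, Lpar2 or Hddc3 singly. Plekhg1 and Hpca had no neighbour in the set. H60a was not placed, so its neighbours could not be counted and the same question stays undecided for it.

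Mast cell and basophil genes had medians of -1.05, -0.90 and -1.61 in the M-CSF, IFNg/LPS and IL-4 genotype effects, past camera's preset test but not with an estimated correlation (adjusted p = 0.47, 0.81 and 0.22). In IFNg/LPS the list did not pass camera with the libraries numbered 2 and 3 only (adjusted p = 0.072). Its median log2 value in p110g-/- IFNg/LPS libraries was 1.93 to 3.14, so members at that level lay near the floor. Fibroblast genes had medians of 1.38 and 1.05 in M-CSF and IL-4, likewise lost with an estimated correlation (0.47 and 0.55), and no library was called contaminated from such markers. In every group the library numbered 1 stood apart from the other 2, and no label explains it.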
